A study of Mus musculus with 5 samples.

How the data were processed

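Total RNA from mouse neuroepithelial cells was measured by RNA sequencing in 5 libraries of 1 group. Per the labels' protocols, cDNA of full length was made with a tailed poly-dT primer and template switching, amplified for 12 cycles, sheared with ultrasound and made into Illumina libraries with 15 further PCR cycles. Single-end reads of 75 bases were taken on a HiSeq 2000, on average 35 M (1 M = 1000000) per sample. No molecular identifiers are described, so PCR copies could not be told from separate molecules, and the labels do not state that strand was kept, so reads of overlapping or antisense genes could not be told apart. Amplified cDNA made from poly-dT can favour some transcripts over others, which affects comparisons between genes more than comparisons of 1 gene between libraries.

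The authors deposited 1 table of FPKM, with 1 value per gene and library. FPKM divides a gene's fragments by its transcript length and by the library's mapped reads in units of 1000000. The submitters' processing notes name CASAVA 1.8, cutadapt, TopHat2 2.0.11, Cuffdiff 2.2.1 and the genome build mm10, with no role or order, and the gene annotation release, the filters and the definition of the mapped-read total are not given in the sources used here. Each of the 5 value columns was matched to its sample by the replicate number in its name. Reads of near-identical copies, such as those of Npm1, Ppia, Ptma, ribosomal protein genes and globins, may have been split or shared in a way the values do not show.

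The 21801 gene identifiers were taken as given, and 21614 of them matched GENCODE M21, an annotation of the same build, from which coordinates were taken. Its symbol was equal for 20664 genes, and 21196 were protein coding. In all 5 libraries 2095 genes were listed at 0, including genes that almost every cell uses, so a 0 can be a failed estimate and is given only as listed at 0, with the value of each library. Xist and Hoxd4, members of the fixed lists, were not analysed here.

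The values are not counts, so no count test was used. The depth behind them was read from the low values. Ratios between libraries of genes under 0.3 FPKM piled up at 1 value per library, taken as the relative depth, which was 1.15, 0.902, 1.24 and 1.01 for replicates 2 to 5 against replicate 1. Between 55.7% and 59.2% of these ratios were ratios of whole numbers up to 8 times that value within 0.2%, so whole read counts could not be recovered for the rest. Single-transcript genes under 0.15 FPKM and longer than 800 bases gave the implied total, 20.6 to 28.4 M, after taking 200 bases off each transcript's length, an offset chosen after the data had been seen from 3 tried because it gave the sharpest peak. At such totals 1 read in a transcript of 2000 bases is worth 0.0196 to 0.0269 FPKM, so levels of a few hundredths of an FPKM rest on single reads and differences between them were not detectable at this depth.

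FPKM were put on the scale log2(FPKM + 1), on which differences of low genes are understated. For each gene above 0 in at least 1 library, limma 3.58.1 in R 4.3.3 fitted an intercept over the 5 libraries and tested it, two-sided and with a variance trend, against the value of 1 FPKM, and a gene was called above or below at a Benjamini-Hochberg adjusted p under 0.05. In simulated data with the means of 19706 genes, 5.05% of 2000 genes set exactly at the level were called, and the test recovered 100% of 50 genes shifted by -0.8, 90% of 50 shifted by -0.4, 92% of 50 shifted by 0.4 and 92% of 50 shifted by 0.8 on the log2 scale. Members of 31 lists of marker, patterning, chromatin, cell cycle, signalling and other genes were counted by call, and each list's mean log2 level was set against 10000 random lists of as many tested genes. The medians of pairs of lists (10 contrasts) and 12 gene pairs were compared within each library by a two-sided exact sign-flip permutation test over the 32 sign patterns, with Benjamini-Hochberg adjustment within each family, so that the smallest possible p was 0.0625, or 0.125 when 1 library was left out. A list's deviation is the median over members with a mean of at least 1 FPKM of the difference from the gene's own 5-library mean.

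The lists, contrasts, pairs, tests and alternatives were fixed before the data were examined, as was the rule for named genes: a roster of 20 genes, the 2 highest members and the lowest member of each main list, the highest member of each other list, both genes of each pair, the 10 genes with the highest mean and the 10 with the largest SD of log2 values among those with a mean of at least 10 FPKM. Of the genes this rule takes, 2 are not reported here. Other list members named beside them were chosen after their values were seen. The alternatives were pseudocounts of 0.5 and 0.1, rescaling each library to a sum of 1000000 FPKM or by its median ratio, levels of 0.5 and 2 FPKM, no filter or a mean of at least 0.1 FPKM, limma without the variance trend or with robust variance, list means in place of medians, bounds of 5 and 20 FPKM for variable genes, and leaving out each replicate in turn. A filter keeping genes above 0 in all 5 libraries was added after the data had been seen. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 did the remaining steps.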

Results

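RNA sequencing measured the transcriptome of mouse neuroepithelial cells (NECs), the dividing epithelial cells of the early neural tube that precede radial glia. The series text describes the cells as purified and places them in the developing neocortex, and names an expression profile of them as the purpose. The labels put all 5 libraries in 1 group as replicates 1 to 5, and the age of the embryos and the way the cells were purified are not given in the sources used here. With no second group, the comparisons the design allows are whether a gene lay above or below 1 FPKM (fragments per kilobase of transcript per 1000000 mapped reads), how gene groups stood against each other within a library, and how the libraries differed. The labels do not say whether the replicates came from separate animals, so p-values measure only the spread between these samples, which may be technical.

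Values were given for 21801 genes. FPKM summed to 747034, 805849, 793559, 847625 and 798664 in replicates 1 to 5, and 18456, 17336, 16275, 16940 and 16830 genes lay above 0. The steps between low values implied totals of 22.8, 26.2, 20.6, 28.4 and 23.1 M reads (1 M = 1000000) behind the unit, so that 1 FPKM in a transcript of 2000 bases stood for 37.1 to 51.0 reads. Pearson's r across genes of log2(FPKM + 1) ran from 0.99 to 0.997 over the 10 pairs of libraries and Spearman's rho from 0.958 to 0.975, with genes not being independent replicates, and no pair held identical values. The median SD of log2(FPKM + 1) was 0.16 over the 10983 genes with a mean of at least 1 FPKM. Unless stated otherwise, a level is the mean FPKM ± SD over the 5 libraries (n = 5).

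Npm1, a nucleolar protein of ribosome assembly, had the highest level at 8828 ± 835 FPKM, followed by H2afz, a histone variant, at 7587 ± 523 and the glycolytic enzyme Eno1 at 6966 ± 472. Ppia (5542 ± 314), Rpl13a (5444 ± 282), Hnrnpk (5429 ± 517), Ptma (5239 ± 329), Rps14 (4871 ± 380), Rpl41 (4858 ± 289) and Rps27 (4719 ± 260) made up the rest of the 10 highest, which together held 7.28% to 7.64% of each library's FPKM. Of the 19706 genes above 0 in at least 1 library, 10316 (52.3%) lay above 1 FPKM, 8167 (41.4%) lay below it and 1223 were called neither way, by limma's moderated test with Benjamini-Hochberg adjusted p under 0.05. Another 2095 genes, 9.61% of all 21801, were listed at 0 in all 5 libraries, among them Actb, Pkm, Eef1a1, Hspa8 and Hsp90ab1. Almost every cell uses these, so a value of 0 is reported only as listed at 0. Requiring a mean of at least 0.1 FPKM left 3495 genes called below 1 FPKM.

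The NECs carried the transcripts of neural progenitors. Of the 12 neural progenitor genes fixed before the data were examined, 11 lay above 1 FPKM and none below, and the counts adjusted over the list alone were the same, here and for each of the 31 lists. At an unadjusted p under 0.05 limma's counts were also the same, except that 5 and not 4 Cajal-Retzius genes lay below. The list's mean log2 level was above 96.8% of 10000 random lists of as many tested genes. Prom1, an apical membrane protein, stood at 88.1 ± 11 FPKM, and Pax6, a transcription factor of forebrain progenitors (ENSMUSG00000027168, chromosome 2, 105668900 to 105697364 on mm10), at 64.6 ± 7.64, which was 5.03 above 1 FPKM on the log2(FPKM + 1) scale (SE 0.07, limma adjusted p = 1.1e-10). The intermediate filament Vim (54.2 ± 8.38), Cdh2 (42.0 ± 4.95) and the SoxB1 factors Sox2 (11.6 ± 1.72), Sox1 (2.17 ± 0.48) and Sox3 (2.10 ± 0.57) were also above the level, as was Nes (3.55 ± 0.67). Sox2 exceeded Sox1 by 1.99 ± 0.03 on the log2 scale in 5 of 5 libraries. Hes5, a Notch target, was called neither way at 0.99 ± 0.33 FPKM. The list's median deviation from the gene means ran from 0.18 in replicate 1 to -0.21 in replicate 3, the libraries lowest and highest for the mesenchyme list. Sox1 was no longer called against a level of 2 FPKM (log2 difference 0.07).

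**Figure D1:**
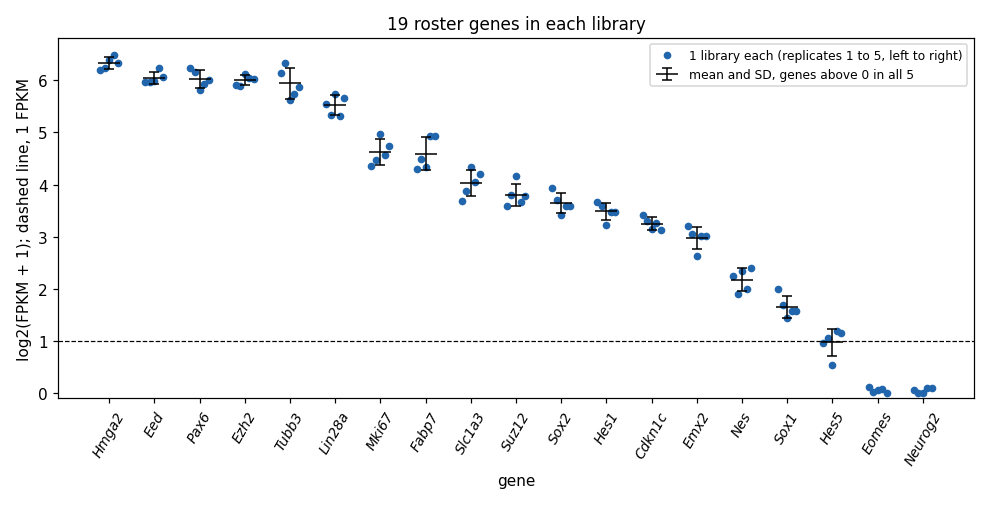
Of the 20 genes fixed as a roster, the 19 reported, on a log2(FPKM + 1) axis: each point is 1 library, the bars are the mean and SD for genes above 0 in all 5 libraries, and the dashed line is 1 FPKM. Hmga2, Eed, Pax6, Ezh2 and Tubb3 lie highest at means of 61.6 to 79.8 FPKM, Hes5 lies at the line, and Eomes and Neurog2 lie near 0.

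Regulators of early developmental timing were among the high transcripts. 10 of the 11 members of that list lay above 1 FPKM and 1 below, with a list median of 64.1 ± 2.96 FPKM and a mean log2 level above all 10000 random lists. The chromatin proteins Hmga1 (241 ± 47.9) and Hmga2 (79.8 ± 6.63), the RNA-binding proteins Igf2bp1 (140 ± 7.58), Igf2bp2 (127 ± 2.77) and Igf2bp3 (64.1 ± 2.96) and the zinc finger factor Sall4 (111 ± 10.2) had the highest levels. Lin28a and Lin28b, which block maturation of the let-7 microRNA, stood at 45.2 ± 6.04 and 49.4 ± 5.40 FPKM and differed by -0.13 ± 0.22 on the log2 scale, with Lin28a higher in 1 of 5 libraries (exact sign-flip permutation test, two-sided, p = 0.312, adjusted 0.375). L1td1 lay below the level at 0.35 ± 0.26 FPKM, but was called neither way against a level of 0.5 FPKM (log2 difference -0.17). Hmga1 has processed copies in the mouse genome, so its level is uncertain where reads could be split.

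In the list of radial glia and astrocyte genes 3 of 10 lay above 1 FPKM, 5 below and 2 were called neither way, and the list's mean log2 level was above 13.3% of the random lists. Fabp7, a fatty acid carrier of radial glia, stood at 23.6 ± 5.44 FPKM, the glutamate transporter Slc1a3 at 15.6 ± 2.90 and the receptor phosphatase Ptprz1 at 4.82 ± 1.03. Hopx (0.36 ± 0.11) and Slc1a2 (0.32 ± 0.16) were below the level, and Bcan was listed at 0.0285, 0.0249, 0, 0 and 0.0282 FPKM in replicates 1 to 5. The median of the early-timing list exceeded that of the radial glia list by 5.35 ± 0.18 on the log2 scale, and the neural progenitor median exceeded it by 2.89 ± 0.21, each in 5 of 5 libraries. For these and all 10 list contrasts the two-sided exact sign-flip permutation test gave p = 0.0625 and an adjusted p = 0.0625, the smallest value 5 libraries allow, so no contrast could pass 0.05.

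Transcripts of committed neuronal progenitors and neurons separated into a low majority and a few abundant genes. In the proneural and basal progenitor list 3 of 12 lay above 1 FPKM, 8 below and 1 neither way. Eomes, the T-box factor of basal progenitors, was listed at 0.0865, 0.0143, 0.0335, 0.0471 and 0 FPKM in replicates 1 to 5, Neurog2 at 0.0432, 0, 0, 0.0696 and 0.0641, and Neurog1 at 0, 0.0262, 0.0332, 0.0242 and 0.0297. Mfng (14.3 ± 2.33), a glycosyltransferase acting on Notch, the antiproliferative factor Btg2 (7.39 ± 1.61) and the Notch ligand Dll1 (5.69 ± 1.61) were the 3 above. Pax6 exceeded Eomes by 5.98 ± 0.16 on the log2 scale in 5 of 5 libraries (exact sign-flip permutation test, p = 0.0625, adjusted 0.0833), whereas Neurog2 and Neurog1 differed by 0.02 ± 0.05, with Neurog2 higher in 3 of 5 (exact p = 0.438, adjusted 0.477).

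Among 14 neuronal genes, 5 lay above 1 FPKM, 8 below and 1 was called neither way. Tubb3, a neuronal tubulin, stood at 61.6 ± 13.1 FPKM, the growth-cone protein Gap43 at 18.2 ± 5.23, Map2 at 13.3 ± 5.01, Stmn2 at 8.53 ± 3.11 and the synaptic protein Snap25 at 2.06 ± 0.54. Slc17a7, a vesicular glutamate transporter, was listed at 0.0639 FPKM in replicate 1 and at 0 in the other libraries. In the Cajal-Retzius list 4 of 7 lay below the level and none above: Reln stood at 1.27 ± 0.26 FPKM and Calb2 at 0.80 ± 0.24, both called neither way, and Trp73 was listed at 0.0096 in replicate 1 and at 0 elsewhere. The neural progenitor median exceeded the neuron median by 3.15 ± 0.11 and the proneural and basal median by 3.32 ± 0.12 on the log2 scale, each in 5 of 5 libraries (exact sign-flip permutation test, p = 0.0625). The neuron list's median deviation was 0.34 in replicate 1 and -0.32 in replicate 3, and the proneural list's 0.26 and -0.29, again the libraries lowest and highest for the mesenchyme list. Without replicate 4 Reln was called above 1 FPKM (log2 difference 0.24), which made the Cajal-Retzius count 1.

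Of the 12 dorsal forebrain genes, 9 lay above 1 FPKM, 2 below and 1 neither way, and the list's mean log2 level was above 75.8% of the random lists, against 0.71% for the ventral, 0.13% for the midbrain and hindbrain and none for the Hox list. The surface ectoderm list was above 71.6% and the mesenchyme list above 57.9%, so a value like the dorsal list's is not particular to forebrain genes. Otx2, a homeobox factor of the forebrain and midbrain (ENSMUSG00000021848, chromosome 14, 48657677 to 48673819), stood at 85.1 ± 12.9 FPKM, Gli3 at 30.9 ± 1.82, Lhx2 at 16.8 ± 4.59 and Emx2 at 6.95 ± 1.11. Emx1 lay below the level at 0.30 ± 0.16 FPKM, and Emx2 exceeded it by 2.61 ± 0.33 on the log2 scale in 5 of 5 libraries. Of the 13 ventral forebrain genes 2 lay above and 9 below: Dlx5 stood at 25.1 ± 9.18 FPKM and Isl1 at 4.24 ± 0.59, while Dlx2 was at 0.17 ± 0.05 and Gsx1 was listed at 0.0278 FPKM in replicate 1 and at 0 in the other libraries. Dlx5 and Isl1 are also expressed outside the ventral forebrain.

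None of the 8 midbrain and hindbrain genes lay above 1 FPKM and 7 lay below, with En1 at 0.52 ± 0.18 FPKM. Pax8 was called neither way at 0.76 ± 0.30, and En2 was listed at 0.0091, 0.0160, 0.0101, 0.0147 and 0 FPKM in replicates 1 to 5. Of the 19 Hox genes measured, which pattern the hindbrain and trunk, 18 lay below the level, among them Hoxb1 at 0.16 ± 0.10 FPKM and Hoxc4, which was listed at 0.0244 in replicate 5 and at 0 elsewhere. Hoxb2, at 1.70 ± 0.25 FPKM, was the 1 above (log2 difference 0.43, SE 0.08, limma adjusted p = 0.0013). The dorsal forebrain median exceeded the ventral by 2.69 ± 0.16, the midbrain and hindbrain by 2.84 ± 0.14 and the Hox median by 2.98 ± 0.11 on the log2 scale, each in 5 of 5 libraries (exact sign-flip permutation test, p = 0.0625). The dorsal list's median deviation ran from 0.18 in replicate 1, lowest for the mesenchyme list, to -0.18 in replicate 3, highest for it. Against a level of 2 FPKM Hoxb2 had a difference of -0.16 and was called neither way, and without replicate 3 Pax8 was called below 1 FPKM (log2 difference -0.27).

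Polycomb genes, whose products modify histones and hold genes silent, were expressed across both complexes. In the Polycomb repressive complex 2 list (PRC2, which methylates histone H3 at lysine 27) 10 of 12 lay above 1 FPKM, 1 below and 1 neither way. The histone-binding subunits Rbbp4 (519 ± 31.4) and Rbbp7 (111 ± 10.9) had the highest levels, the core subunits Eed, Ezh2 (ENSMUSG00000029687, chromosome 6, 47530139 to 47595341) and Suz12 stood at 65.1 ± 5.63, 63.2 ± 4.37 and 13.1 ± 2.26 FPKM, and Phf1 was at 0.12 ± 0.03. Ezh2 exceeded its homolog Ezh1 (8.72 ± 1.26) by 2.73 ± 0.23 on the log2 scale in 5 of 5 libraries. In the PRC1 list 14 of 19 lay above and 4 below, with the ubiquitin ligase Rnf2 at 89.4 ± 5.79 FPKM and Pcgf2 at 30.3 ± 6.37. Cbx2 (5.91 ± 1.12) exceeded Cbx7 (0.49 ± 0.14) by 2.21 ± 0.23, and the PRC2 median exceeded the PRC1 median by 0.70 ± 0.19, both in 5 of 5 libraries. Cbx7, called below 1 FPKM, was called neither way against 0.5 FPKM (log2 difference -0.02).

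All 16 genes for methylation of histone H3 at lysine 4 and for removal of methyl groups from lysines 4 and 27 lay above 1 FPKM, from Kmt2a at 3.41 ± 0.62 to Kdm5a at 41.1 ± 1.8 and Dpy30, a subunit shared by the methylase complexes, at 332 ± 24.8. The lysine 27 demethylases Kdm6a (7.39 ± 1.27) and Kdm6b (6.53 ± 0.85) differed by 0.15 ± 0.37 on the log2 scale, with Kdm6a higher in 3 of 5 libraries (exact sign-flip permutation test, p = 0.5, adjusted 0.5). Of 12 DNA methylation genes 11 lay above the level. Uhrf1, which brings the maintenance methylase to replicated DNA, stood at 303 ± 27 FPKM, and the maintenance methylase Dnmt1 at 107 ± 9.52. Dnmt3l, the 1 gene below, was listed at 0, 0.184, 0.425, 0.169 and 0.120 FPKM in replicates 1 to 5. The de novo methylase Dnmt3a (106 ± 5.13) exceeded Dnmt3b (16.3 ± 2.14) in 5 of 5 libraries, the difference of Dnmt3b minus Dnmt3a being -2.63 ± 0.24, and Tet1 (12.9 ± 1.77) exceeded Tet3 (3.55 ± 0.51) by 1.61 ± 0.08. Of the 12 gene pairs fixed before the data were examined, 9 differed in the same direction in 5 of 5 libraries, each with an exact sign-flip p = 0.0625 and an adjusted p = 0.0833.

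**Figure D2:**
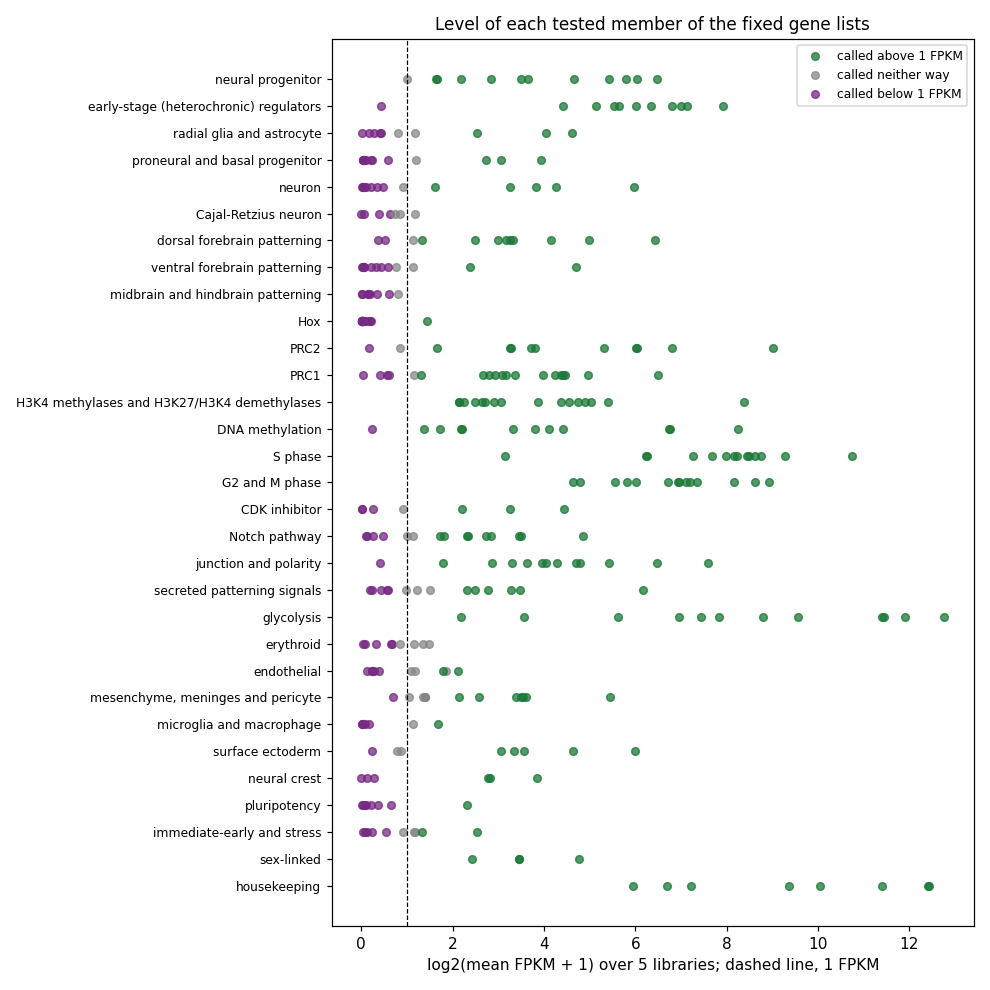
Mean level of every tested member of the 31 fixed gene lists on a log2(mean FPKM + 1) axis, 1 point per gene, coloured by its limma call against 1 FPKM, which the dashed line marks. All 14 S-phase and all 14 G2 and M phase genes lie above the line, and 18 of 19 Hox genes lie below it.

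All 14 S-phase genes lay above 1 FPKM, with a list median of 292 ± 13.4 FPKM, led by Rrm2, a subunit of ribonucleotide reductase, at 1720 ± 119 and the replicative helicase subunit Mcm7 at 616 ± 52.9, and lowest for the licensing factor Cdt1 at 7.89 ± 1.34. All 14 G2 and M phase genes lay above it too, from Mki67 at 23.9 ± 4.41 to Ccnb1 at 396 ± 56.9 and Cdk1 at 489 ± 89.6. The G2 and M median minus the S-phase median was -1.25 ± 0.10 on the log2 scale, with S phase higher in 5 of 5 libraries. Among the CDK inhibitors 3 of 7 lay above the level, Cdkn2d at 20.7 ± 1.87 FPKM, Cdkn1c at 8.55 ± 0.80 and Cdkn1b at 3.59 ± 0.56, and 3 below, among them Cdkn2a, which was listed at 0.0664 in replicate 5 and at 0 elsewhere. The G2 and M list's median deviation was -0.24 in replicate 1, lowest for the mesenchyme list too, and 0.19 in replicate 4.

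The 12 measured glycolysis genes all lay above 1 FPKM, with Eno1 at 6966 ± 472, Ldha, which makes lactate, at 3821 ± 159, Aldoa at 2800 ± 132 and Gapdh at 2702 ± 169 FPKM. Pkm, the 13th member, was listed at 0 in all 5 libraries. All 8 measured housekeeping genes lay above the level, with Actb listed at 0.

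Of 13 genes of junctions and apical polarity 12 lay above 1 FPKM. The catenins Ctnna1 and Ctnnb1 stood at 191 ± 18.2 and 88.1 ± 20.6 FPKM, and Crb1 was below the level at 0.33 ± 0.10. Cdh2, the neural cadherin, exceeded Cdh1, the epithelial cadherin (25.2 ± 5.67 FPKM), by 0.73 ± 0.35 on the log2 scale in 5 of 5 libraries. Like the surface ectoderm list, Cdh1 was lowest in replicate 1 (19.8 FPKM) and highest in replicate 2 (32.6 FPKM). Which cells carried Cdh1 was not tested. In the Notch list 9 of 15 lay above the level and 4 below: the nuclear effector Rbpj stood at 28.1 ± 1.48 FPKM, Hes1 at 10.3 ± 1.27, the ligand Jag1 at 9.88 ± 0.69 and Notch1 at 6.19 ± 1.97, while Dll3 was listed at 0.255, 0, 0.104, 0 and 0 FPKM in replicates 1 to 5. Hes5 minus Hes1 was -2.51 ± 0.20. Of 14 secreted patterning signals 6 lay above and 5 below, with Fgf15 at 71.4 ± 17.4 FPKM, Bmp7 at 10.1 ± 1.02, Wnt5a at 8.77 ± 2.05 and Wnt8b at 5.85 ± 0.56, and with Shh at 0.35 ± 0.08 and Bmp6 at 0.14 ± 0.05.

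Markers of other cell types differed in level from type to type. In the mesenchyme, meninges and pericyte list 8 of 12 lay above 1 FPKM and 1 below, with Lum, a matrix proteoglycan (ENSMUSG00000036446, chromosome 10, 97565128 to 97572703), at 42.6 ± 21.9 FPKM, Pdgfra at 11.2 ± 4.57, Pdgfrb at 10.7 ± 3.89 and Col1a2 at 10.3 ± 3.44. In the surface ectoderm list 5 of 8 lay above and 1 below, with the keratins Krt18 at 62.3 ± 11.8 and Krt8 at 24.1 ± 5.16 and with Epcam at 10.9 ± 2.37, and in the neural crest list 3 of 6 lay above and 3 below, led by Tfap2b at 13.3 ± 3.82. Simple epithelia and neuroepithelium can also carry Krt8, Krt18 and Epcam. The other surface ectoderm members above the level were Grhl3 at 9.16 ± 2.76 and Trp63 at 7.30 ± 1.73 FPKM. The endothelial count was 2 of 10 above, Pecam1 at 3.32 ± 0.46 and Esam at 2.46 ± 1.48 FPKM, and 5 below. It was 1 without replicate 3, 4 or 5, and 3 without replicate 1 or 2. In the microglia and macrophage list 1 of 7 tested genes lay above, Cd68 at 2.21 ± 0.95 FPKM, and 5 below, with 3 more listed at 0, and Cd68 was called neither way against 2 FPKM (log2 difference 0.04).

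No erythroid gene lay above 1 FPKM: 5 of 9 tested lay below, 3 more were listed at 0, and the embryonic globin Hbb-y was called neither way at 1.79 ± 1.06 FPKM. Without replicate 1 Hbb-y was called above (log2 difference 0.55), for a count of 1. In the pluripotency list 7 of 8 lay below the level, with Nanog, which has processed copies in the mouse genome, above it at 3.97 ± 1.24 FPKM. Of 10 immediate-early and stress genes, which rise on tissue handling, 2 lay above and 5 below, with Fos at 4.83 ± 2.5 and Dusp1 at 1.52 ± 0.14. The 4 measured Y-linked genes, led by Eif2s3y (ENSMUSG00000069049, chromosome Y, 1010543 to 1028847) at 26.0 ± 15.5 FPKM, all lay above 1 FPKM.

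The median deviation of a list spanned the widest range between libraries for the Y-linked genes (1.79), followed by the mesenchyme (1.21), erythroid (1.16) and endothelial (1.09) lists. Lum was at 12.1, 28.2, 66.1, 55.5 and 50.9 FPKM in replicates 1 to 5, and the mesenchyme list's median deviation was -0.74, -0.37, 0.46, 0.23 and 0.33 on the log2 scale. The endothelial list's was -0.48, -0.32, 0.24, 0.61 and 0.48 over 5 genes, the erythroid list's -0.12, -0.40, 0.02, 0.75 and 0.22 over 3 genes and the neural crest list's -0.44, -0.04, 0.29, -0.06 and 0.18 over 3 genes. The neural progenitor median minus the mesenchyme median was 1.29 ± 0.81, above 0 in 5 of 5 libraries but ranging from 0.35 in replicate 3 to 2.27 in replicate 1 (exact sign-flip permutation test, p = 0.0625). Eif2s3y was at 25.6, 51.3, 26.7, 13.5 and 13.2 FPKM, with a deviation of the 4 Y-linked genes from -0.68 in replicate 5 to 1.12 in replicate 2. Over the 5861 genes with a mean of at least 10 FPKM the median deviation stayed between -0.09 and 0.07. A median over 3 or 5 low genes varies more by chance, and no range for sets of like size and level was computed.

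**Figure D3:**
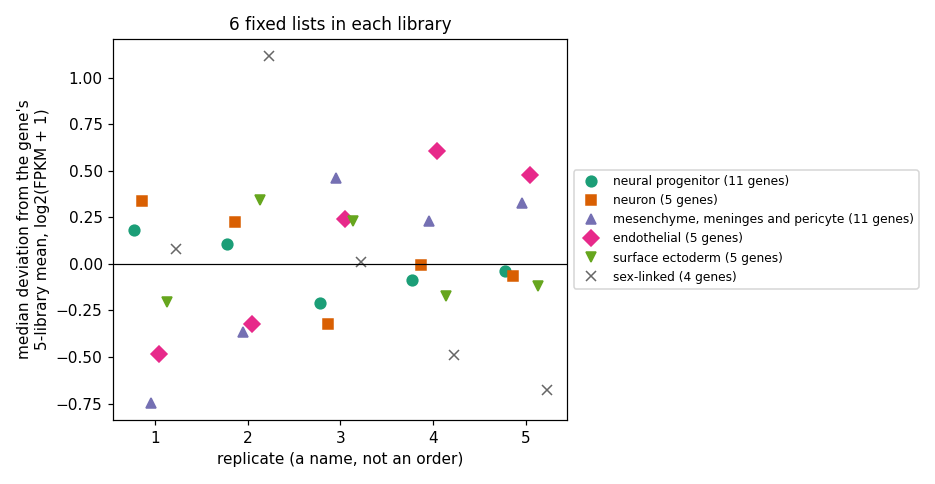
Median deviation of 6 fixed lists from each gene's 5-library mean, on the log2(FPKM + 1) scale, for members with a mean of at least 1 FPKM; each symbol is 1 list in 1 library and the line at 0 is the mean. The mesenchyme list lies at -0.74 in replicate 1 and 0.46 in replicate 3, the Y-linked genes lie at 1.12 in replicate 2, and the neural progenitor list stays between -0.21 and 0.18.

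Among the genes with a mean of at least 10 FPKM, 75 had an SD of log2(FPKM + 1) above 0.5, and 32 did without replicate 1. The 10 with the largest SD were all predicted gene models. Gm10800 (ENSMUSG00000075014, chromosome 2, 98666547 to 98667301) was at 448, 117, 61, 70.5 and 103 FPKM in replicates 1 to 5, its neighbour Gm10801 at 70.6, 19.9, 8.64, 11.3 and 16.1, Gm21738 at 38.0, 9.39, 4.31, 6.12 and 8.58 and Gm11032 at 241, 186, 78.7, 91.5 and 28.1. The others had values of 0: Gm17571 was listed at 217, 94.5, 0, 69.8 and 42.8 FPKM, Gm17387 at 91.9, 80.2, 0, 0 and 0, and Gm10985 at 92.6, 0, 0, 24.9 and 0. Gm11114 and Gm17631 were listed above 0 in replicate 1 alone, at 205 and 53.1 FPKM, and Gm16499 in replicate 2 alone, at 53.9. The bound on the SD was set after the data had been seen.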

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

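The tests on the X-linked copies and on sequencing depth and the choice of patterns to weigh were made after the values had been seen. For the share of male cells, the value of 1.48 met the condition written beforehand, a median of at least 1, and the explanation was set back to open by a further condition added after the values had been seen, that the other Y-linked genes follow the 4 fixed ones between replicates 1 and 2. The comparison of losses and gains of X-linked and Y-linked copies was also added then, and turned shared reads from excluded to open. For genomic DNA or other background, the ratio of 1.9 met the condition written beforehand, at least 1.5, and the explanation was set back to open because the genes tested are part of the excess. Of 171 values examined across the 5 libraries, 18 had 1 library whose gap to its nearest neighbour, divided by the range, was above Dixon's critical value for 5 samples. Chance gives about 1 in 20, but 7 of the 18 are among the 10 genes chosen for the largest SD between libraries and 8 are genes above 0 in 1 library, for which the ratio is always 1, so the 18 cannot be set against chance. Without both kinds of gene, a count made after the values had been seen, 6 of 156 values remained, against 7.8 by chance: 2 each in replicates 2 and 3 and 1 each in replicates 1 and 4.

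Most of the distant values in replicate 1 belong to predicted gene models or to genes near 0. Gm10800 was at 448 FPKM there against 61 to 117 in the other libraries, Gm10801 at 70.6 against 8.64 to 19.9, Gm21738 at 38.0 against 4.31 to 9.39 and Gm10985 at 92.6 against 0 to 24.9. Gm11114 (205 FPKM), Gm17631 (53.1), Slc17a7 (0.0639), Trp73 (0.0096) and Gsx1 (0.0278) were listed above 0 in replicate 1 and at 0 in the other libraries, and Neurog1 was listed at 0 in replicate 1 against 0.0242 to 0.0332 elsewhere.

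Replicate 1 also had the most genes above 0, 18456 against 16275 to 17336. Olfactory and vomeronasal receptor genes, which brain progenitors are not known to use, were above 0 in 655 of 1381 cases in replicate 1 and in 345, 151, 234 and 246 in replicates 2 to 5, a ratio of 1.9 to the next library. Their FPKM summed to 154.8 in replicate 1 and to 40.27, 17.37, 24.53 and 28.15 in replicates 2 to 5. A higher sum does not by itself tell genomic DNA from another source. Deeper sequencing is argued against, since 3 libraries had a higher depth than replicate 1. Reads from genomic DNA or another background that does not come from RNA stay open: the receptor genes are 310 of the 1120 genes by which replicate 1 exceeded replicate 2, so the ratio of 1.9 partly restates the excess and cannot tell this source from others. The design gives 1 group, so no biological explanation was tested.

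The median of the 4 Y-linked genes was 20.5 FPKM in replicate 2 against 5.18 to 9.29 in the other libraries. Eif2s3y, Ddx3y, Uty and Kdm5d were 3.90, 4.28, 3.68 and 3.64 times as high in replicate 2 as in replicate 5, the libraries with the highest and lowest median. Reads shared with the X-linked copies stay open: Eif2s3x, Ddx3x, Kdm6a and Kdm5c had a median log2 ratio of -0.50 (-0.503) between the same libraries, and Eif2s3x and Ddx3x lost 75.1 and 39.1 FPKM where Eif2s3y and Ddx3y gained 38.2 and 15.6, but Kdm6a and Kdm5c lost 2.45 and 0.0768 where Uty and Kdm5d gained 15 and 6.94. A different share of male cells in each library may be the source, but cannot be told from the 3 other chromosome Y genes: their median log2 ratio was 1.48, from 1.48 (Gm21719), -1.18 (Gm21778) and 1.69 (Erdr1), and replicate 1, the library with the most low genes above 0, had 7.56 FPKM of Gm21719 and 2.11 of Gm21778 against 2.95 and 0.142 in replicate 2, with Erdr1 at 25.7 and 24.2, where the 4 Y-linked genes were lower (median log2 ratio -1.14, SD 0.07). In replicates 3 to 5 Gm21719 was at 0.394 to 1.055 FPKM and Gm21778 at 0 to 0.3205, so their ratios rest on low values and could not decide. Beyond the share of male cells no biological explanation was tested, since the labels give no sex.

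Gli3 was at 34.1 FPKM in replicate 3 against 29.7 to 30.7 in the others. Hoxc4 (0.0244 FPKM) and Cdkn2a (0.0664) were listed above 0 in replicate 5 and at 0 in the others, and Gm16499 was at 53.9 (53.95) FPKM in replicate 2 and listed at 0 in the others. The midbrain and hindbrain list's median was 0.231 FPKM in replicate 4 against 0.0666 to 0.107 in the others. Tet1 minus Tet3 was 1.75 on the log2 scale in replicate 2 against 1.56 to 1.59, and Emx2 minus Emx1 was 2.03 in replicate 3 against 2.68 to 2.80.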

How the results depend on the processing

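One alternative, the filter keeping genes above 0 in all 5 libraries, was chosen after the data had been seen. No paired analysis was possible because the labels give 1 group. The 12 pairs kept their direction in all 108 alternatives run and the 10 contrasts in all 100, where no p-value could pass 0.05; the 31 list counts stayed within 1.5 times in 477 of 496. The number of genes called above 1 FPKM was 10195 to 10668 in the alternatives that kept this level, and 11495 genes lay above 0.5 FPKM and 9034 above 2 FPKM. The number of genes called below 1 FPKM fell from 8167 to 3495 with a mean of at least 0.1 FPKM and to 3563 with genes above 0 in all 5 libraries, because fewer low genes were tested (15007 and 15024). Rescaling to a sum of 1000000 raised the median of the 10983 genes with a mean of at least 1 FPKM by 0.30 (log2). For 114 named genes 1753 of 1786 alternatives gave the same call and direction, 4 lost the call, 12 gained one and 17 reversed. Members above the level, where the count moved, were: Cajal-Retzius (0) 1 at a sum of 1000000, 2 against 0.5 FPKM, 1 without the variance trend and 0 to 1 with a replicate left out; erythroid (0) 2, 3 and, with a mean of at least 0.1 FPKM, 1, and 0 to 1 with a replicate left out; endothelial (2) 5 against 0.5, 1 against 2 FPKM, 1 with no filter and 1 to 3 with a replicate left out; microglia (1) 2 and 0, and immediate-early (2) 5 and 1, against 0.5 and 2 FPKM; Hox (1) 0 against 2 FPKM. The log2 difference reversed against 0.5 FPKM for Hes5 (0.39), Calb2 (0.25), Pax8 (0.21) and En1 (0.0099), and against 2 FPKM for Reln (-0.41), Hoxb2 (-0.16), Hbb-y (-0.18), Gm11114 (-0.05, -0.047), Gm16499 (-0.43) and Gm17631 (-0.43); moving the level itself shifts these differences. Hes5 reversed at a sum of 1000000 (0.14) and without replicate 3 (0.08, 0.084), uncalled both times, with a range of -0.08 (-0.079) to 0.08 over the left-out replicates. Pseudocounts of 0.5 and 0.1 reversed Gm16499 (-0.23, -1.64) and Gm17631 (-0.24, -1.65), and 0.1 reversed Gm11114 (-1.26), each listed at 0 in 4 libraries. Variable genes numbered 127 with a mean of at least 5 FPKM and 34 with at least 20, and 32 to 98 with a replicate left out, 32 being without replicate 1. The median SD, 0.16, was 0.18 with a pseudocount of 0.1, which widens differences of low genes. The cause of the other changes was not tested.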

Other observations

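The gene families, the genes Alx1 and Bgn and the test on neural share were chosen after values had been seen. For the share of mesenchymal cells, the condition written beforehand would have excluded the explanation, because a second gene set had another lowest library than the fixed list, and the further condition that this gap exceed its spread was added after the values had been seen and left it open. For the share of neural cells, the condition first set would have excluded it, and the condition that at least 3 surface ectoderm genes not carried by neuroepithelium be counted was added later and left it open. In all, 25 families were taken by gene symbol and counted by limma call against 1 FPKM, and those not repeated from the report follow. Among transcription factors, 11 of 19 Sox genes lay above 1 FPKM, led by Sox4 (21.7 ± 0.93 FPKM, SD, n = 5) and Sox9 (19.2 ± 4.12), all 6 genes of the homeobox family of Six3 (8.5 ± 2.17) and Six4 (6.03 ± 1.08) lay above it, and 4 of 5 Zic genes did, led by Zic5 (8.32 ± 1.25). All 6 Irx genes and 33 of 34 tested Hox genes lay below. The craniofacial Alx genes lay above in 3 of 3 cases, Dlx in 2 of 6 (Dlx5 and Dlx3), Msx in 1 of 2 (Msx1) and Tfap2 in 2 of 5 (Tfap2b and Tfap2c). Among guidance and Wnt receptor genes, 8 of 14 Eph receptors lay above, led by Epha7 (64.1 ± 7.86), 6 of 8 ephrins, 8 of 20 semaphorins, led by Sema3a (26.9 ± 5.38), and 6 of 10 Frizzled receptors, led by Fzd3 (13.1 ± 2.52).

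Of the 6 enzymes that make or break down retinoic acid 1 lay above 1 FPKM, Aldh1a3 at 97.3 ± 27.6 FPKM. Pcdhgc4 (50.5 ± 6.88) was the 1 of 23 tested clustered protocadherins above the level and shares exons with its neighbours, so its value is uncertain. Ribosomal protein genes held 17.4 ± 0.28% of each library's FPKM, with 81 of 84 above 1 FPKM, and the 13 mitochondrially encoded genes 1.86 ± 0.40%. Above the level were also 44 of 45 complex I subunits, 36 of 39 tested proteasome subunits, 24 of 35 tested kinesins, 5 of 36 tested keratins, 4 of 18 tested Gabr subunits, 1 of 577 tested olfactory receptors (Olfr613) and 1 of 235 tested vomeronasal receptors (Vmn1r58), the last 2 at 13.0 and 13.7 FPKM in replicate 1 and at 3.94 or less in the other libraries. Rescaling to a sum of 1000000 moved these counts above the level by at most 1, rescaling by the median ratio moved none, and leaving out replicate 1 took the Gabr count to 2 and moved the others by at most 1. Without replicate 1 the counts below the level fell from 576 to 364 for olfactory and from 233 to 177 for vomeronasal receptors. Genes above 0 in replicate 1 alone were not tested once it was left out, so fewer receptors tested can lower these counts. Over all genes, 18831 were tested without replicate 1 against 19706 with it.

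The fixed mesenchyme list's median deviation was lowest in replicate 1 and highest in replicate 3, 1.21 (log2) apart, and Alx1, at 7.86, 17.2, 36.3, 27.8 and 28.8 FPKM in replicates 1 to 5, and Bgn, at 3.29, 5.12, 13.3, 15.9 and 13.7, were also lowest in replicate 1. Scaling of whole libraries is argued against by a range of 0.15 (0.153) over all genes with a mean of at least 10 FPKM. A lower share of neural cells, which would raise every other type alike, stays open: between replicates 1 and 3 the neural progenitor list went from 0.18 to -0.21 and the neuron list from 0.34 to -0.32 while the endothelial (-0.48 to 0.24) and neural crest (-0.44 to 0.29) lists went with mesenchyme, but in replicate 2 the surface ectoderm list was at 0.34 (SD 0.10) where the mesenchyme list was at -0.37 (-0.366, SD 0.21), and neuroepithelium can carry 3 of its 5 counted genes, leaving Trp63 (0.38) and Grhl3 (0.56). Between replicates 1 and 3 the proneural list also fell, from 0.26 to -0.29. The radial glia and astrocyte list, over 4 genes, went with mesenchyme instead, from -0.265 to -0.030. Gap43, 1 of the neuron list's 5 counted genes, rose too, from 11.9 to 23.4 FPKM. A different share of mesenchymal cells in each library may be the source and stays open: the 6 genes with a mean of at least 1 FPKM among 15 other mesenchymal genes, chosen before their values were seen, had a range of 0.70 (0.703), but their lowest library was replicate 2, not replicate 1, by a median of 0.25 with an SD of 0.44 between genes. The labels call the cells purified without naming a sort, 2 of the list's 11 counted genes (Pdgfra and Foxd1) are also known from neural tissue, and beyond these cell shares no biological explanation was tested, since the labels give 1 group.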
